A study of Mus musculus with 10 samples.

How the data were processed

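RNA of mouse plantaris muscle was measured on Affymetrix Mouse Gene 2.1 ST array strips. Per the labels' protocols, RNA was extracted with Qiazol, and equal amounts from 4 muscles were pooled for each array. The labels are not uniform on how the RNA was labelled: the sample descriptions name the GeneChip WT PLUS kit, and the labelling protocol names NuGEN Ovation PicoSL amplification from 10 ng of total RNA followed by biotin labelling of 3.75 µg of cDNA. Both statements appear for every sample, so the kit used for each array is not known here. The authors deposited 1 table of log2 expression values, with 41345 probe sets and 10 arrays. Per the submitters' processing notes, the tools were RMA, oligo and limma, without versions. RMA corrects the background, quantile-normalizes probe intensities between arrays and summarizes probes by median polish. It compresses changes of dim genes and assumes similar intensity distributions in all groups, so a shift shared by most transcripts is not measured. That the deposited values are on the log2 scale was read from their range of -0.45 to 12.71. No scanner intensities were used here, so the background correction was kept as deposited, and strip and scan date are not given in the sources used here.

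Groups were taken from the sample labels. They were no overload, 3 d of overload, 3 d of overload with a PDGF inhibitor, 10 d of overload and 10 d of overload with the inhibitor, with 2 pools each. Pools were numbered 1 and 2 within a group as names only, and nothing pairs them across groups. The labels do not say whether the pools of a group came from different animals, so p-values measure only the spread between these pools, part of which may be technical.

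Of the probe sets, 23521 had exactly 1 gene symbol in the array annotation, 1814 had several and 16010 were not listed. Probe sets with exactly 1 symbol gave 22180 genes. Where a gene had several probe sets (1082 genes), the brightest over all arrays stood for it. No gene was filtered out for dim signal.

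Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 10 arrays, and tested with empirical Bayes moderation. The fit had 5 residual degrees of freedom per gene and 3.58 prior degrees of freedom, and the prior SD was 0.18 log2 units. There were 7 comparisons: each overload time against no overload, 10 d against 3 d of overload, the inhibitor against none at each time, the mean of these inhibitor effects, and their difference. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 22180 genes of a comparison. Values after ± are standard errors of the log2 change from this fit, and every adjusted p of a gene comes from it.

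The comparisons, gene lists, marker lists, naming rule and other ways of analysis listed below were fixed before the data were examined. The 32 lists covered signalling, matrix, fibre, metabolic and inflammatory genes and markers of cell types that muscle can hold. The red blood cell list had too few measured members (minimum 4), which left 31. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 31 lists, and again with the correlation estimated from the data and with fry. Camera asks whether a list's members shifted relative to other genes. A list score is the median, over its members, of each gene's value minus its mean over the 10 arrays. Per comparison, the text names the 6 largest rises and 6 largest falls among changed genes whose groups did not overlap (for the averaged effect and the difference of effects, overlap was ignored), leaving out symbols without an assigned name and olfactory, vomeronasal, small RNA and antigen receptor segment genes. It also names up to 4 changed members with the largest change of each list that was called or had at least 3 changed members, and the 6 PDGF ligands and receptors. Where fewer than 6 genes passed, the 6 with the smallest p were given as values. Members completing a count of at most 5, and any other member, were named after their values were seen. Lists of red cell precursor, platelet, granulocyte precursor and B cell precursor genes were added after the data were seen.

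The same steps were tested on simulated data for 22180 genes, of which 200 were changed by a known fold, in 20 simulations per comparison. For 3 d of overload against none, 89.0% of 4-fold, 33.6% of 2-fold and 0.821% of 1.5-fold changes were recovered. For the inhibitor at 10 d the shares were 89.8%, 32.7% and 1.04%. False calls were 5.54% and 4.99% of all calls in these comparisons. In simulated lists of 20 genes for the inhibitor at 10 d with no shift but a residual correlation of 0.5, the preset correlation called 53% and the estimated correlation called 0% of 100 lists. With a shift of 0.5 log2 units and the same correlation, the shares were 99% and 7%. The preset therefore called too many correlated lists here, and the estimate missed most true shifts of such lists.

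The other ways were an intensity trend in the variance, a fit on the compared groups alone, quantile normalization of the table again, a common median of the tested genes, omission of the dimmest 30% of genes, a test of every probe set, the mean of a gene's probe sets, a minimum change of 1.5-fold, array weights, and omission of each array in turn. In the last, the lone array left in a group was assumed to vary like the other groups. Leaving out an array of a group that a comparison does not use keeps its log2 changes. It alters only the estimate of the spread and lowers its degrees of freedom.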

Results

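The plantaris, a muscle of the calf, was overloaded in male C57BL/6 mice by synergist ablation, in which muscles that share its work are removed. Some of the mice received an inhibitor of platelet-derived growth factor (PDGF) signalling, whose name is not given in the sources used here. PDGFs are growth factors that act on fibroblasts, pericytes and other mesenchymal cells through the receptors Pdgfra and Pdgfrb. Transcripts were measured without overload, after 3 d and 10 d of overload, and after 3 d and 10 d of overload with the inhibitor, in 2 pools of 4 muscles per group. Array medians over all probe sets lay between 2.40 and 2.45 log2 units. Pools of a group correlated across genes at r = 0.989 to 0.992. Pool 1 of 10 d overload was as close to a 10 d inhibitor pool as to its own partner (r = 0.989 for both). The first principal component carried 43.1% of the variance and ran from the pools without overload (51.3 and 48.5) to the 3 d overload pools (-45.7 and -37.0).

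The first question was how muscle transcripts responded to 3 d of overload. Sprr1a, a small proline-rich protein induced in stressed tissue, rose 124-fold against no overload (log2 6.96 ± 0.33, adjusted p = 2.84e-05, n = 2 pools per group). Tenascin C (Tnc), a matrix glycoprotein of loaded and healing tissue, rose 38.3-fold, the protease inhibitor Timp1 36.4-fold, and sarcolipin (Sln), which binds the calcium pump of the sarcoplasmic reticulum, 24.4-fold. Ms4a7, a macrophage membrane protein, rose 31.7-fold and the proliferation marker Mki67 24.2-fold. The largest falls by the naming rule were 18.7-fold for Odf3l2, 13.1-fold for Lrrc52, a potassium channel subunit, 12.6-fold for Klhl33 and 11.7-fold for Gbp10. The polyamine enzyme Smox fell 8.43-fold and Plin5, a lipid droplet protein, fell 7.95-fold. Without single arrays Sln ranged from log2 3.95 to 5.27 and Ms4a7 from 4.32 to 5.65.

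Of 26 measured cell cycle genes, 22 rose, and all 26 rose when adjusted over the list alone. Ccnb2, a cyclin of mitosis, rose by log2 4.35, Top2a, which untangles replicated DNA, by 4.02 ± 0.19, and the mitotic motor Kif11 by 3.53 ± 0.20. This list was called with the preset correlation (camera adjusted p = 7.83e-24) and with an estimated correlation (adjusted p = 0.0104). All 19 macrophage and monocyte genes rose, also adjusted over the list alone, among them Cd68 (22.6-fold), the integrin subunit Itgam (14.4-fold) and the Fc receptor Fcgr1, with adjusted p = 0.127 with an estimated correlation. Of 20 cytokines and chemokines, 11 rose (12 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation), led by the chemokines Ccl2 (19.7-fold), Ccl6 (12.2-fold), Ccl9 (10.9-fold) and Ccl7 (10.1-fold). Of 12 neutrophil genes, Lcn2 and Csf3r rose (3 adjusted over the list alone; adjusted p = 0.314 with an estimated correlation), by log2 2.63 ± 0.31 and 1.59 ± 0.13. Beside this list, 3 d overload pool 1 stood apart from its partner, with neutrophil list scores of 1.64 and -0.58. The same pool held Elane at 5.21 and Mpo at 5.02 log2 units, enzymes made by granulocyte precursors of bone marrow, against at most 1.75 for each gene in the other 9 pools. Without it, the neutrophil list shifted by 0.16 and was not called (camera adjusted p = 0.121). Bst2, Oasl2 and Stat2 rose among 14 interferon response genes, a list that was not called (camera adjusted p = 0.0716). No gene passed in the lymphocyte (median 0.07) or mast cell list (median -0.01).

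Matrix genes and genes of growing fibres also rose at 3 d. Of 22 fibrillar and interstitial matrix genes, 18 rose (19 adjusted over the list alone; adjusted p = 0.219 with an estimated correlation), including periostin (Postn, 22.6-fold), the collagen cross-linking enzyme Lox (17.9-fold) and Col3a1 (8.12-fold). Among 14 basement membrane genes, 6 rose (7 adjusted over the list alone; adjusted p = 0.264 with an estimated correlation), Col15a1 by 1.04 ± 0.14, Col4a2 by 0.95, Col4a1 by 0.91 and Lamc1 by 0.87 ± 0.13. Of 16 matrix proteases and inhibitors, 8 rose, after Timp1 most in Adam12, Mmp14 and Mmp19, and Timp3 fell (9 and 1 adjusted over the list alone; adjusted p = 0.230 with an estimated correlation). Protease list scores were 0.81 in 3 d overload pool 1 and 0.06 in its partner, and the median of 1.40 was 0.78 without pool 1 and 1.96 without the partner. In the fibroblast list of 17 genes, 7 rose, led by Mfap5, S100a4, Cd248 and Thy1, while Clec3b and Gsn fell (8 and 3 adjusted over the list alone; adjusted p = 0.314 with an estimated correlation). Of 14 embryonic and regenerating fibre genes, 13 rose (13 adjusted over the list alone; adjusted p = 0.0768 with an estimated correlation), including the load-responsive Ankrd1 (18.3-fold), the myosin light chain Myl6b (6.57-fold), embryonic myosin Myh3 (6.25-fold) and the fetal acetylcholine receptor subunit Chrng (6.12-fold). The fusion gene Mymk rose 21.2-fold and the muscle transcription factor Myog 9.98-fold, ahead of Itga7 and Ncam1, within the satellite cell and myoblast list, in which 8 of 14 genes rose and Chrdl2 fell (8 and 1 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation). Of 6 PDGF ligands and receptors, Pdgfc rose (log2 1.42 ± 0.32, adjusted p = 0.0168), and Pdgfra (0.46 ± 0.16), Pdgfrb (0.09 ± 0.16), Pdgfa (-0.43 ± 0.15), Pdgfb (0.36 ± 0.22) and Pdgfd (0.23 ± 0.17) did not pass. Pdgfc ranged from 1.15 to 1.69 without single arrays and was lost without either 3 d overload pool or no-overload pool 1 (adjusted p up to 0.105). That list was not called (camera adjusted p = 0.173), and adjusted over the list alone 2 of its genes rose and 1 fell.

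Energy metabolism moved the other way. Of 19 fatty acid oxidation genes, 16 fell (17 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation), among them the nuclear receptor Ppara (3.81-fold), the uncoupling protein Ucp3 (3.26-fold), Eci1 (2.55-fold) and the acyl-CoA dehydrogenase Acadvl (2.54-fold). Of 16 genes of glycolysis and glycogen, 12 fell (14 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation), most in Gpd1 (log2 -2.18 ± 0.17), the phosphorylase kinase subunits Phkg1 (-1.76 ± 0.15) and Phka1 (-1.09), and Pfkm. A dimmer second probe set of Gpd1 gave -0.92. Ppara ranged from log2 -2.52 to -1.34 without single arrays and was kept in 8 of 10 omissions. Of 26 oxidative phosphorylation genes, 18 fell (24 adjusted over the list alone; adjusted p = 0.219 with an estimated correlation), Cox7a1 by 2.50-fold, followed by Cox5b, Uqcrfs1 and Ndufb8, and a dim second probe set of Cox5b gave -0.45. Of 14 fast fibre genes, 4 fell (6 adjusted over the list alone; adjusted p = 0.219 with an estimated correlation): Mylk2, Pvalb, Mybpc2 and Tnni2. The call of Tnni2 was lost whichever array was left out. In the atrophy and autophagy list, Klf15, Fbxo32 (the ubiquitin ligase atrogin-1), Ulk1, Bnip3 and 3 others of 17 fell, and Gabarapl1 rose (7 and 2 adjusted over the list alone; adjusted p = 0.219 with an estimated correlation). Among 10 slow fibre genes, Casq2 and Tnnt1 rose and Myh7 and Myl3 fell, and the list was not called (camera adjusted p = 0.520).

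Signalling and secretion lists were also called at 3 d. Among 22 immediate early and feedback genes, 11 rose and Etv5 fell (11 and 1 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation), with the stress transcription factor Atf3 13.3-fold, the phosphatase Dusp5 4.75-fold, Egr3 4.04-fold and Myc 3.61-fold higher. Of 19 genes of the unfolded protein response and secretion list, 14 rose, while Ddit3 and Herpud1 fell (14 and 2 adjusted over the list alone; adjusted p = 0.193 with an estimated correlation). Its largest rises were in Plod2 and Serpinh1, which act in collagen maturation, Sdf2l1 and Pdia3. Of 21 TGF-beta and BMP genes, 6 rose, led by Ltbp2, Tgfb1 (3.79-fold), Tgfbi and Id2, and Acvr2b and Mstn, a myostatin receptor and myostatin itself, fell (7 and 3 adjusted over the list alone; adjusted p = 0.219 with an estimated correlation). Of 17 IGF genes, 6 rose, led by Igf1 (2.38-fold), Igfbp7 and Igfbp4, and Igfbp5 fell (6 and 1 adjusted over the list alone; adjusted p = 0.270 with an estimated correlation). Nop58, Nip7, Gnl3 and Noc2l rose among 19 ribosome biogenesis genes (4 adjusted over the list alone; adjusted p = 0.149 with an estimated correlation). List medians ranged without single arrays from 0.57 to 1.09 for immediate early, 0.23 to 0.51 for TGF-beta, 0.17 to 0.34 for IGF and 0.55 to 1.03 for satellite cell genes. Vessel-related lists were not called. Hgf, Angptl4, Apln and Hif1a rose and Vegfb and Vegfa fell among 17 angiogenic factors (camera adjusted p = 0.169). Tie1, Flt1 and Aqp1 fell among 15 endothelial genes (0.171). Mcam and Tagln rose and Lmod1 and Kcnj8 fell among 13 pericyte and smooth muscle genes (0.871).

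At 3 d, 3881 of 22180 genes passed, 2066 higher and 1815 lower. Shifting each array to a common median removed 0.19 log2 units, the difference between the array medians of these groups. The split was then 1567 higher and 3295 lower. The median change over genes was -0.04 before this shift, so most genes did not share that difference. The count was 2146 without overload pool 1, 2582 without overload pool 2 and 2427 without the no-overload pool 1, with 2023, 2395 and 2249 of the genes shared. Of 105 genes named at 3 d, 81, 87 and 85 passed in these cases. The IGF call was lost without overload pool 1 or no-overload pool 1 (camera adjusted p = 0.121 and 0.0857), the atrophy call without no-overload pool 2 (0.0921), and these lists and ribosome biogenesis were lost at a common median (0.0509 for each).

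After 10 d of overload, sarcolipin had risen 49.1-fold against no overload (log2 5.62 ± 0.38, adjusted p = 8.17e-04, n = 2 pools per group). Postn rose 21.3-fold, C1qtnf3, a secreted protein of connective tissue, 33.8-fold, and P4ha3, a prolyl hydroxylase of collagen, 15.8-fold. The developmental myosins Myh8 and Myh3 rose 17.5-fold and 17.1-fold, and a dim second probe set of Myh8 gave log2 0.81. Without single arrays C1qtnf3 ranged from log2 3.60 to 6.56 and was lost without no-overload pool 2 (adjusted p = 0.0613), and P4ha3 ranged from 2.85 to 5.12 and was lost without no-overload pool 1 (0.0696). Sln ranged from 4.96 to 6.28 and Myh8 from 3.25 to 5.02. Lrrc52 fell 6.45-fold, Neto2, an auxiliary subunit of glutamate receptors, 5.69-fold, the zinc transporter Slc30a2 5.12-fold, Odf3l2 5.12-fold, Slc15a5 4.99-fold and the extraocular myosin Myh13 4.67-fold. Myh13 passed in 5 of 10 omissions (log2 -2.69 to -1.75, adjusted p up to 0.168), Lrrc52, Odf3l2 and Slc15a5 in 8 and Slc30a2 in 9.

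Of 22 fibrillar and interstitial matrix genes, 18 rose (20 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation), with Col3a1 10.4-fold, Tnc 8.77-fold and Col1a1 7.10-fold higher. Of 14 basement membrane genes, 11 rose (12 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation), Col15a1 and the laminin chain Lamb1 by 1.56 each, Col4a2 by 1.51 ± 0.17 and Col4a1 by 1.36. Of 16 matrix proteases and inhibitors, 8 rose (8 adjusted over the list alone; adjusted p = 0.183 with an estimated correlation), with the membrane metalloprotease Mmp14 8.86-fold, Timp1 8.68-fold, the collagen-degrading cathepsin Ctsk 8.37-fold and Adam12 7.83-fold higher. Adam12 ranged from log2 2.01 to 3.92 and was lost without either no-overload pool (adjusted p up to 0.0747), and Ctsk from 2.45 to 3.68, lost without no-overload pool 1 (0.0536). Mmp14 ranged from 2.48 to 3.81 and Tnc from 2.53 to 3.74 and passed throughout. Without single arrays the protease median ran from 0.60 to 1.36 and the tendon median from 0.56 to 1.31. Of 17 fibroblast genes, 10 rose, led by Mfap5, Lum, Thy1 and Pi16 (11 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation), and of 10 tendon genes Tnmd, Thbs4, Scx and Cpxm2 rose (6 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation). A dim second probe set of Cpxm2 gave -0.25. The 10 d overload pools were unequal here, with matrix list scores of 0.47 and 1.41 and tendon list scores of 0.26 and 1.05 in pools 1 and 2. Pdgfra, the PDGF receptor of fibroblasts, rose (log2 0.82 ± 0.16, adjusted p = 0.0269), and Pdgfrb (0.54 ± 0.16), Pdgfd (0.62 ± 0.17), Pdgfc (0.70 ± 0.32), Pdgfb (0.31 ± 0.22) and Pdgfa (-0.20 ± 0.15) did not pass. Pdgfra ranged from 0.63 to 1.02 without single arrays and was lost without 10 d overload pool 2 or either no-overload pool (adjusted p up to 0.151). Adjusted over the list alone, 3 of the 6 PDGF genes rose (adjusted p = 0.157 with an estimated correlation).

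Dividing-cell, macrophage, and embryonic and regenerating fibre genes remained high as lists. Of 26 cell cycle genes, 15 rose (18 adjusted over the list alone), Mki67 8.08-fold, Ccnb2 7.36-fold, Top2a 4.27-fold and Kif11 4.10-fold, and the call held with an estimated correlation (adjusted p = 0.0321). Of 19 macrophage genes, 15 rose (18 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation), most in Ms4a7, the complement genes C1qa and C1qb, and Fcgr1. Of 14 embryonic and regenerating fibre genes, 11 rose (11 adjusted over the list alone; adjusted p = 0.0667 with an estimated correlation), after the developmental myosins most in Ankrd1 and the cardiac actin Actc1. The slow fibre genes Tnnt1, Casq2, Tnnc1 and Atp2a2 rose among 10 measured (5 rose and 2 fell adjusted over the list alone; adjusted p = 0.168 with an estimated correlation). Igf2, Igfbp4, Igf1 and Igfbp7 rose among 17 IGF genes (7 adjusted over the list alone; adjusted p = 0.185 with an estimated correlation), Igf2 by 6.80-fold. Of 21 TGF-beta and BMP genes, 6 rose, led by Bmp1, the myostatin antagonist Fst, Id2 and Tgfb1, and Mstn fell 2.24-fold (6 and 2 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation). Ccl8, Ccl9 and Ccl6 rose among 20 cytokines (4 adjusted over the list alone; adjusted p = 0.219 with an estimated correlation). Atf3 and Spred1 rose among 22 immediate early genes (3 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation). Acadvl, Eci1 and Etfa fell among 19 fatty acid oxidation genes (10 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation). The call of Etfa was lost whichever array was left out, and that of Eci1 in most omissions. Cox5a fell among 26 oxidative phosphorylation genes (5 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation). Glycolysis genes shifted by a median of -0.27, with 1 fall adjusted over the list alone (adjusted p = 0.219 with an estimated correlation). Oasl2 rose among 14 interferon response genes (1 adjusted over the list alone; adjusted p = 0.272 with an estimated correlation), and Gjc3 and Sox10 fell among 8 Schwann cell genes (2 adjusted over the list alone; adjusted p = 0.221 with an estimated correlation). Atrophy and ribosome biogenesis genes had medians of -0.30 and -0.13 without a member that passed, also adjusted over the list alone (adjusted p = 0.192 and adjusted p = 0.168 with an estimated correlation). Plod2, Serpinh1 and Pdia3 rose among 19 secretion genes, a list that was not called (camera adjusted p = 0.168). Apln and Nrp2 rose and Vegfb fell among 17 angiogenic factors, also not called (0.0767). Among these genes Ms4a7 ranged from log2 2.86 to 4.19, Actc1 from 1.80 to 3.03 and Plod2 from 1.80 to 3.15 without single arrays, and Actc1 and Plod2 passed in 9 of 10 omissions. List medians ranged from 0.10 to 0.37 for IGF, 0.17 to 0.31 for TGF-beta, 0.23 to 0.57 for immediate early, 0.19 to 0.38 for cytokine, 0.13 to 0.44 for interferon, -0.43 to -0.20 for oxidative phosphorylation and -0.23 to -0.13 for ribosome genes.

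At 10 d, 1138 genes passed, 865 higher and 273 lower. At a common median, which removed a difference of 0.17 log2 units between array medians, the split was 678 higher and 896 lower. The median change over genes was -0.04 before this shift. The count was 324 without overload pool 2, 259 without no-overload pool 1 and 525 without no-overload pool 2, and 285, 232 and 406 of these were among the 1138. Of 76 genes named at 10 d, 47, 34 and 49 passed in these cases. The satellite cell list, in which Mymk, Myog, Ncam1, Megf10 and Itga7 rose (5 rose and 1 fell adjusted over the list alone; adjusted p = 0.195 with an estimated correlation) and whose median ranged from -0.02 to 0.34, was not called without no-overload pool 1 (camera adjusted p = 0.0736), and the calls of ribosome biogenesis (without overload pool 1, 0.0579, or no-overload pool 1, 0.0917), atrophy and interferon response (without overload pool 2, 0.0525 and 0.289, or no-overload pool 2, 0.137 and 0.0762) and Schwann cells (without overload pool 1, 0.121, or no-overload pool 2, 0.196) were also lost.

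Called genes overlapped between the times. Of the 865 genes higher at 10 d, 666 were also higher at 3 d, and of 273 lower genes 218 (79.9%) were also lower. Independent lists of these sizes would share 80.6 and 22.3 genes. Unchanged groups simulated against the shared no-overload pools shared 0 and 0.02 genes. Few genes pass in such groups, so this count is near 0 by design and cannot measure what shared pools add. The changes correlated across genes at r = 0.721, with a covariance of 0.211 against 0.0254 in the simulation. Genes are not independent replicates, and with 2 no-overload pools part of the excess may come from the shared controls.

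The next question was what changed between 3 d and 10 d of overload. Sprr1a fell 47.8-fold (log2 -5.58 ± 0.33, adjusted p = 9.48e-04, n = 2 pools per group), Ccl2 14.1-fold, Cgref1 8.01-fold, the small GTPase Rrad 7.23-fold, the TWEAK receptor Tnfrsf12a 7.18-fold and the syntrophin Sntb1 6.97-fold. Ky, a muscle protein needed for normal growth, rose 7.54-fold, Klhl33 7.04-fold, Snai3 6.73-fold, the tendon gene Tnmd 6.18-fold, Dupd1 5.26-fold and Gbp10 5.14-fold. Without single arrays Ccl2 ranged from log2 -4.93 to -2.70 and Cgref1 from -4.09 to -1.91. Ccl2 was lost without 3 d overload pool 1 (adjusted p = 0.0870), Cgref1 without either 3 d overload pool (up to 0.105), Rrad without these or 10 d overload pool 1 (up to 0.0706), and Dupd1 passed in 2 of 10 omissions. Of 26 cell cycle genes, 17 fell (22 adjusted over the list alone), Plk1, a mitotic kinase, by 4.17-fold, Top2a by 3.80-fold, Cenpe by 3.79-fold and the replication gene Mcm5 by 3.58-fold, and the call held with an estimated correlation (adjusted p = 0.0167). Nop58, Gnl3, Noc2l and Nip7 fell among 19 ribosome biogenesis genes (9 adjusted over the list alone), a list also called with an estimated correlation (adjusted p = 0.0413).

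Of 19 macrophage genes, 11 fell (18 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation), Cd68 by 6.15-fold, Ccr2 by 4.22-fold, Gpnmb by 3.63-fold and Itgam by 3.55-fold. Of 20 cytokines, 8 fell, after Ccl2 most in Ccl6, Ccl7 and Cxcl5 (9 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation). Lcn2 and Csf3r fell among 12 neutrophil genes (6 adjusted over the list alone; adjusted p = 0.258 with an estimated correlation), a list in which 3 d overload pool 1 stood apart. Of 19 secretion genes, 9 fell, most in Sdf2l1, the chaperone Hspa5, Pdia6 and Xbp1, and Herpud1 rose (13 and 1 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation). Myog, Myod1, Itga7 and Myf6 fell among 14 satellite cell genes (5 adjusted over the list alone; adjusted p = 0.196 with an estimated correlation). Metabolic genes rose. They were Gpd1, Phkg1, Phka1, Pygm and Tpi1 among 16 of glycolysis (10 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation). Acads, Hadhb, Acadvl and Cpt2 rose among 19 of fatty acid oxidation (11 adjusted over the list alone; adjusted p = 0.196 with an estimated correlation). So did Cox7a1, Uqcrfs1, Sdhb and Ndufa8 among 26 of oxidative phosphorylation (8 adjusted over the list alone; adjusted p = 0.296 with an estimated correlation). Lamb1, Nid1, Nid2 and Lama2 rose among 14 basement membrane genes (10 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation), and Mylk2, Mybpc2, Pvalb and Actn3 among 14 fast fibre genes (4 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation). The calls of Sdhb, Ndufa8, Lama2 and Actn3 were lost whichever array was left out. Fibrillar matrix genes had a median change of 0.41, while the members that passed, Tnc and Lox, fell (4 rose and 2 fell adjusted over the list alone; adjusted p = 0.717 with an estimated correlation). Lox ranged from log2 -2.39 to -1.07 and passed in 7 of 10 omissions, and Tnc from -2.73 to -1.52 and in 9. The neutrophil median ranged from -2.84 to -0.61 and the satellite cell median from -0.69 to -0.37. A second probe set each of Nid1 and Ndufa8 gave 0.84 and 0.80.

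Other muscle and connective tissue lists were called as well. Myh7, Tnnt1 and Tnnc1 rose among 10 slow fibre genes, Myh7, the slow myosin, by 4.68-fold (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.2 with an estimated correlation). Xirp1, Ankrd1, Nes, Csrp3 and Ankrd2 fell and Myh3 rose among 14 embryonic and regenerating fibre genes (7 fell and 2 rose adjusted over the list alone; adjusted p = 0.222 with an estimated correlation). Clec3b, Pi16 and Smoc2 rose among 17 fibroblast genes (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.326 with an estimated correlation). Tnmd rose among 10 tendon genes (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.506 with an estimated correlation) and Tie1 among 15 endothelial genes (5 adjusted over the list alone; adjusted p = 0.219 with an estimated correlation). Atf3, Dusp5 and Ier3 fell among 22 immediate early genes (6 adjusted over the list alone; adjusted p = 0.304 with an estimated correlation). Medians ranged without single arrays from 0.22 to 0.44 for slow fibre, -0.66 to -0.36 for embryonic, 0.17 to 0.54 for fibroblast, 0.26 to 0.91 for tendon, 0.23 to 0.43 for endothelial and -0.60 to -0.14 for immediate early genes. Further lists were not called. Timp1 fell and Mmp2 and Timp3 rose among proteases (camera adjusted p = 0.828). Acvr2b rose and Tgfb1 and Inhba fell in TGF-beta signalling (0.604). Igf2 and Igfbp5 rose and Eif4ebp1 fell in IGF signalling (0.314), with the Eif4ebp1 call lost whichever array was left out. Klf15, Ulk1 and Fbxo32 rose and Gabarapl1 fell among atrophy genes (0.126).

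In all, 1348 genes passed, 598 higher and 750 lower at 10 d than at 3 d. The count was 218 without 3 d overload pool 1, 468 without 3 d overload pool 2, 490 without 10 d overload pool 1 and 878 without 10 d overload pool 2, with 191, 409, 388 and 657 genes shared. Of 86 genes named between the times, 26, 38, 40 and 61 passed in these cases. Calls were lost for matrix and tendon genes without 3 d overload pool 2 (camera adjusted p = 0.130 and 0.218) or 10 d overload pool 2 (0.210 and 0.409), slow fibre genes without 3 d overload pool 2 (0.0510), immediate early genes without 3 d overload pool 1 (0.155), embryonic genes without 10 d overload pool 1 (0.205) and fibroblast genes without 10 d overload pool 2 (0.102), and without this last pool the matrix median was -0.02.

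**Figure D1:**
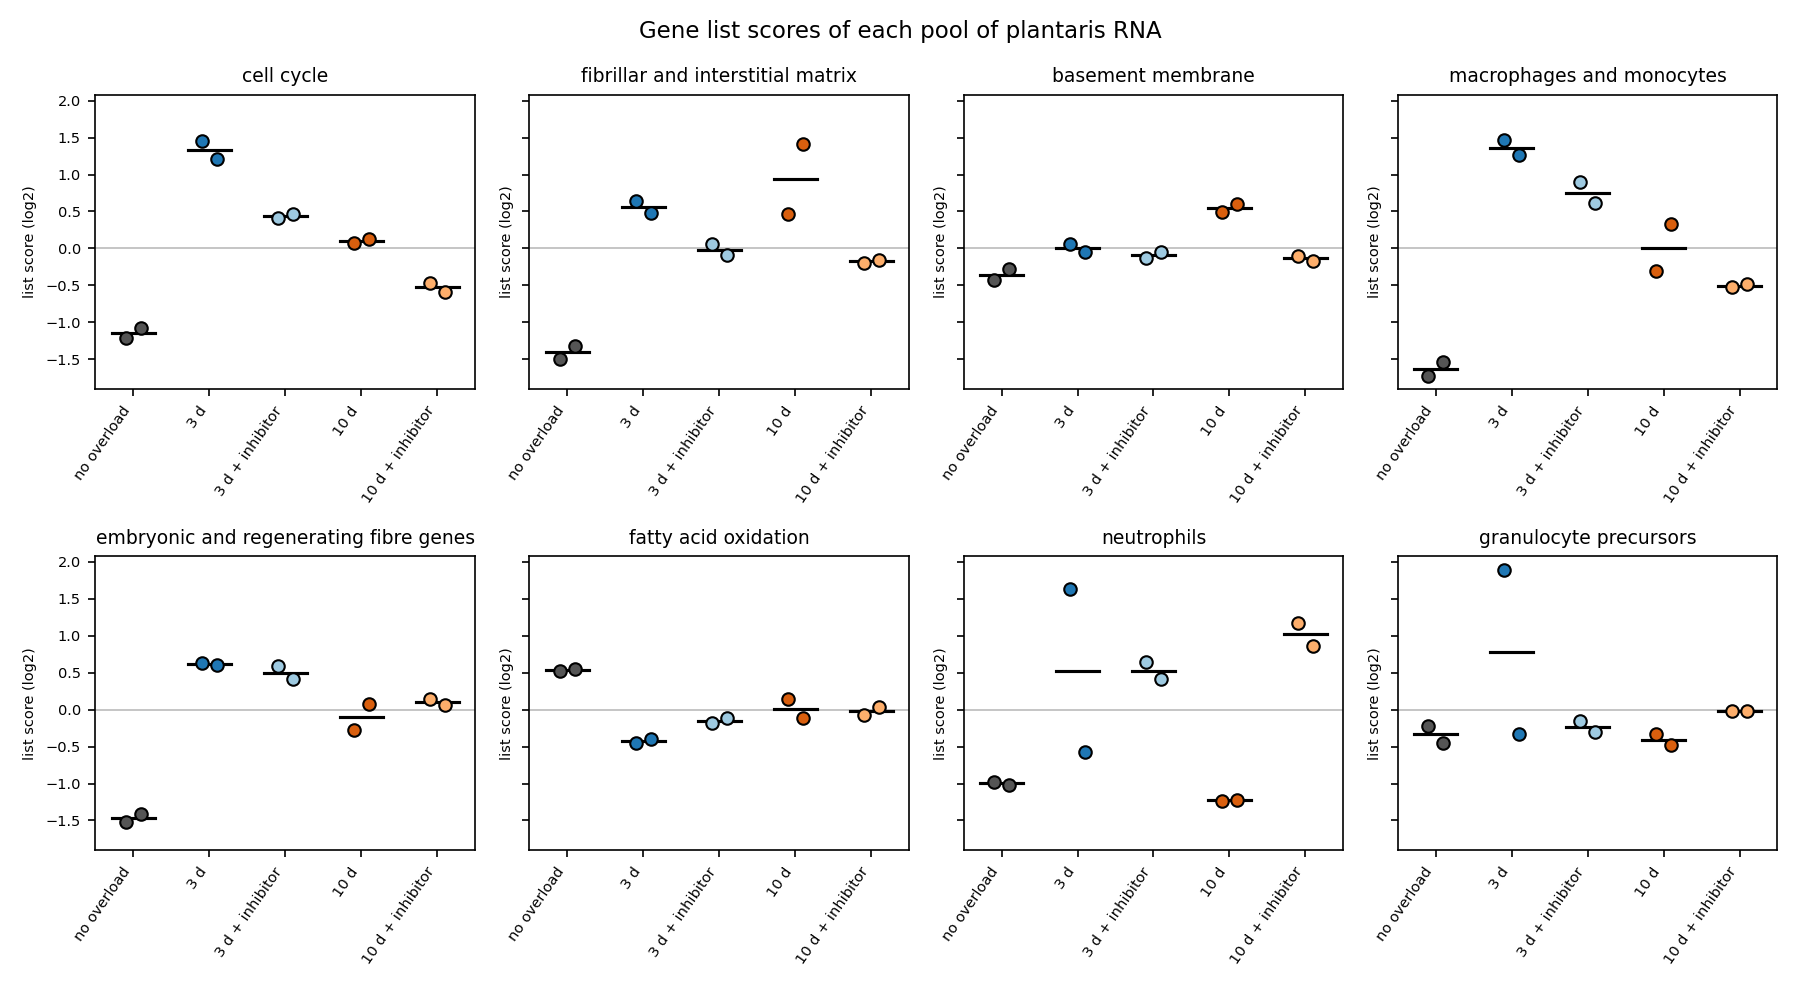
Scores of 8 gene lists (log2, median over members of each gene's value minus its mean over the 10 arrays) for each pool of plantaris RNA, with points for pools and a bar for the mean of the 2 pools of a group. Cell cycle scores of the inhibitor pools were 0.41 and 0.47 at 3 d, below 1.46 and 1.21 without inhibitor, and 3 d overload pool 1 had a granulocyte precursor score of 1.90 against -0.32 in its partner.

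The study's main question was how blocking PDGF signalling altered the response to overload. No group received the inhibitor without overload. An altered response to overload therefore cannot be told apart from an effect that the inhibitor would also have without overload. With the inhibitor at 3 d, no single gene passed, and the shift lay in lists. All 26 cell cycle genes had lower means with the inhibitor, with a median of -0.76, and 11 fell when adjusted over the list alone. The list was called with the preset correlation (camera adjusted p = 6.85e-20) and with an estimated correlation (adjusted p = 0.0160). The genes with the smallest p values included Aspm, a mitotic spindle protein (log2 -1.43 ± 0.14, adjusted p = 0.0907, n = 2 pools per group), the cell cycle phosphatase Cdkn3 (-1.27 ± 0.16) and Hmgb2, a chromatin protein (-1.03 ± 0.13). Map3k7cl (-1.27 ± 0.15), Ctxn3 (1.67 ± 0.18) and the lipase Abhd6 (0.97 ± 0.12) completed the 6, and none of these passed.

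Other lists were called at 3 d with the preset correlation only. Fibrillar matrix genes had a median of -0.56 (20 of 22 negative; adjusted p = 0.567 with an estimated correlation), fibroblast genes of -0.31 (4 fell adjusted over the list alone; adjusted p = 0.541 with an estimated correlation) and tendon genes of -0.63 (5 fell adjusted over the list alone; adjusted p = 0.567 with an estimated correlation). Macrophage genes had a median of -0.50, and 2 of 19 fell adjusted over the list alone (adjusted p = 0.541 with an estimated correlation). Without single arrays these medians ranged from -0.95 to -0.25 for tendon, -0.38 to -0.17 for fibroblast and -0.74 to -0.30 for macrophage genes, and the tendon scores of the 3 d overload pools were 0.21 and -0.30. Fatty acid oxidation genes had a median of 0.25, with 17 of 19 positive (adjusted p = 0.541 with an estimated correlation). Adjusted over the list alone, no matrix or fatty acid oxidation gene passed. Immediate early genes had a median of 0.39 and endothelial genes of 0.20 (adjusted p = 0.567 and adjusted p = 0.600 with an estimated correlation), or 0.09 to 0.62 and 0.13 to 0.26 without single arrays. Basement membrane and secretion genes had medians of -0.15 and -0.19 (adjusted p = 0.610 with an estimated correlation for each), and atrophy genes a median of 0.10, with 1 rise adjusted over the list alone (adjusted p = 0.541 with an estimated correlation). Their ranges without single arrays were -0.22 to -0.05, -0.21 to -0.08 and 0.05 to 0.27. The PDGF receptors gave -0.12 ± 0.16 for Pdgfra and 0.22 ± 0.16 for Pdgfrb, and the ligands 0.11 ± 0.15 for Pdgfa, 0.25 ± 0.22 for Pdgfb, -0.59 ± 0.32 for Pdgfc and -0.19 ± 0.17 for Pdgfd. Beside these lists, 3 d overload pool 1 held granulocyte precursor transcripts and its partner did not.

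By limma, 0 of 22180 genes passed for the inhibitor at 3 d, while 2011 had an unadjusted p under 0.05, against 1109 by chance, and 7 passed without 3 d overload pool 2. Calls were lost for basement membrane, atrophy and secretion genes without 3 d overload pool 1 (camera adjusted p = 0.526, 0.0582 and 0.526) or 3 d inhibitor pool 1 (0.141, 0.178 and 0.0702), secretion genes also without inhibitor pool 2 (0.183), immediate early genes without overload pool 2 (0.387) or inhibitor pool 1 (0.0606), and endothelial genes without overload pool 2 (0.184) or inhibitor pool 2 (0.356).

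At 10 d the inhibitor changed 23 genes. Prnd, which encodes the prion-like protein doppel of new blood vessels, fell 9.99-fold (log2 -3.32 ± 0.32, adjusted p = 0.0256, n = 2 pools per group), and a dim second probe set of it gave 0.12. H2-Ab1, a chain of MHC class II, fell 3.69-fold, the acyltransferase Agpat4 3.67-fold and the transcription factor Sox4 3.29-fold, whose dim second probe set gave -0.01. Of mitotic genes, Top2a fell 3.07-fold and Prc1, a spindle protein, 2.94-fold. The 5 genes that rose were Lcn2 (6.57-fold) and Csf3r (2.35-fold), of the neutrophil list, the thrombin receptor gene F2rl2 (3.96-fold), Wnt4 (2.95-fold) and Ctxn3 (2.50-fold). Lcn2 and Csf3r need not mark neutrophils alone. In 3 d overload pool 2 they were at 5.92 and 4.54 log2 units, while S100a8 and Retnlg of that list were at 2.05 and 1.62.

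Matrix and cell division lists were lower with the inhibitor at 10 d. Fibrillar matrix genes had a median of -1.14, and 18 of 22 fell adjusted over the list alone (camera adjusted p = 3.27e-18; adjusted p = 0.242 with an estimated correlation). Among 14 basement membrane genes, Lamb1 (-1.20 ± 0.16) and Col15a1 (-1.09 ± 0.14) fell, and 11 fell adjusted over the list alone (adjusted p = 0.175 with an estimated correlation). Of 17 fibroblast genes, 12 fell adjusted over the list alone (median -0.58; adjusted p = 0.194 with an estimated correlation), as did 5 of 10 tendon genes (median -0.68; adjusted p = 0.264 with an estimated correlation). Beside these lists, 10 d overload pool 2 had a matrix score of 1.41 against 0.47 in its partner, and without it the matrix median was -0.64. Top2a was the cell cycle gene that passed, 12 of 26 fell adjusted over the list alone, and the median was -0.60 (camera adjusted p = 2.35e-12; adjusted p = 0.0528 with an estimated correlation). Macrophage genes had a median of -0.54 with all 19 negative, and none of them passed adjusted over the list alone (adjusted p = 0.322 with an estimated correlation). Without single arrays the medians ranged from -0.85 to -0.27 for macrophage, -1.62 to -0.64 for matrix and -0.99 to -0.33 for tendon genes, and the macrophage scores of the 10 d overload pools were -0.31 and 0.33. Matrix proteases and inhibitors had a median of -0.42 (5 fell adjusted over the list alone; adjusted p = 0.392 with an estimated correlation), slow fibre genes of -0.28 (4 fell adjusted over the list alone; adjusted p = 0.264 with an estimated correlation) and angiogenic factors of -0.26 (2 fell adjusted over the list alone; adjusted p = 0.242 with an estimated correlation). Pericyte and secretion genes had medians of -0.22 and -0.10 (adjusted p = 0.194 and adjusted p = 0.519 with an estimated correlation). Without single arrays these medians ranged from -0.80 to -0.23 for protease, -0.38 to -0.15 for slow fibre, -0.36 to -0.08 for angiogenic, -0.33 to -0.14 for pericyte and -0.21 to -0.07 for secretion genes.

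In the neutrophil list, all 12 genes had higher means with the inhibitor at 10 d, with a median of 2.25, Lcn2 and Csf3r rose, and 8 rose adjusted over the list alone (camera adjusted p = 2.35e-12; adjusted p = 0.242 with an estimated correlation). List scores were 1.18 and 0.86 in the inhibitor pools and -1.24 and -1.22 in the others at 10 d. The red cell anion exchanger Slc4a1 was at 6.16 and 5.15 log2 units in the inhibitor pools against 3.04 and 1.55 and did not pass (adjusted p = 0.219). The PDGF genes did not pass, with Pdgfra at -0.57 ± 0.16, Pdgfrb at -0.39 ± 0.16, Pdgfa at -0.06 ± 0.15, Pdgfb at 0.33 ± 0.22, Pdgfc at -0.33 ± 0.32 and Pdgfd at -0.26 ± 0.17 (1 fell adjusted over the list alone).

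Of the 23 genes, 5 rose and 18 fell, and at a common median 7 rose and 10 fell. With all arrays, 2352 genes had an unadjusted p under 0.05. The 3 d and no-overload pools do not enter this comparison. Leaving one of them out kept every log2 change, so losses in those omissions reflect only the estimate of the spread. By limma, the count was 180 without 10 d overload pool 1, 0 without 10 d overload pool 2, 10 d inhibitor pool 2 or either 3 d inhibitor pool, 1 without 10 d inhibitor pool 1, and 2 without either no-overload pool. Of 13 genes named here, 12 passed without 10 d overload pool 1, and 7 without either 3 d overload pool. Calls were lost for slow fibre and pericyte genes without overload pool 1 (camera adjusted p = 0.148 and 0.0982), protease, secretion and angiogenic genes without overload pool 2 (0.102, 0.539 and 0.207), slow fibre, secretion and angiogenic genes without 10 d inhibitor pool 1 (0.0992, 0.0960 and 0.0960), pericyte and angiogenic genes without 10 d inhibitor pool 2 (0.0637 and 0.0586) and angiogenic genes without either 3 d inhibitor pool (0.0508).

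**Figure D2:**
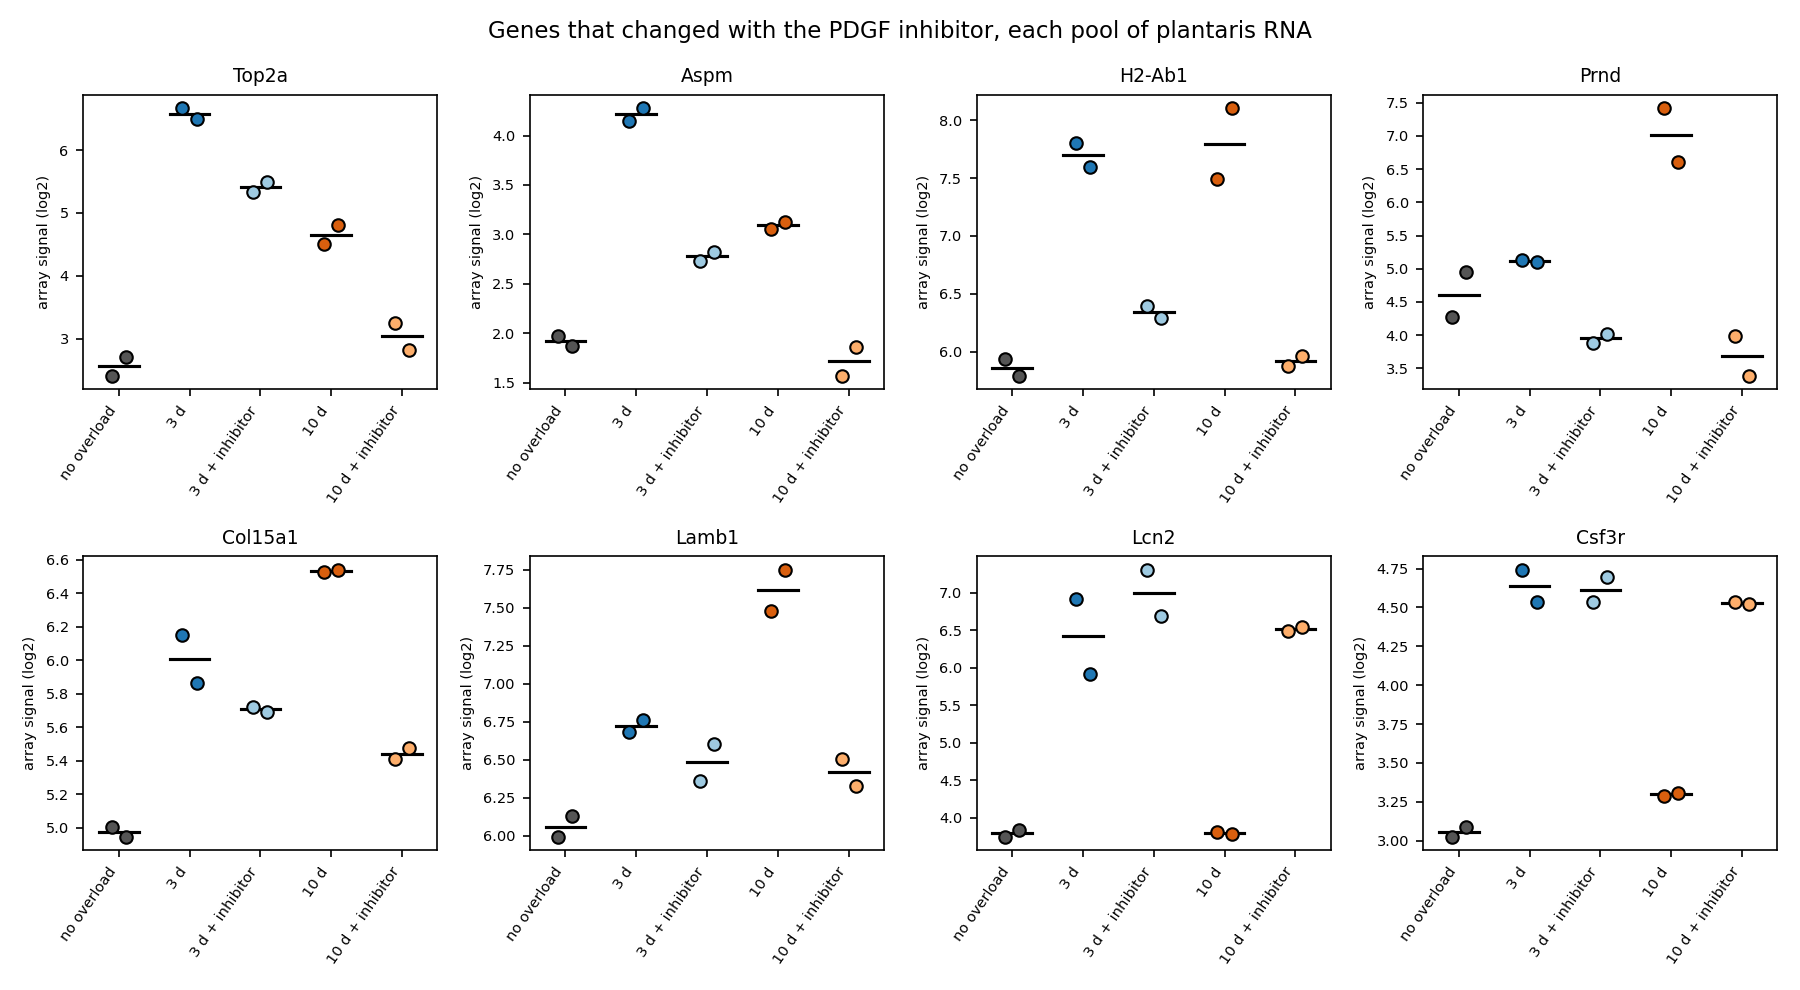
Array signal (log2) of 8 genes named for the inhibitor, with points for pools of plantaris RNA and a bar for the mean of the 2 pools of a group. Top2a fell by 1.62 and Lcn2 rose by 2.72 with the inhibitor at 10 d, and calls at 10 d were lost when single pools were left out.

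Averaging the inhibitor effects over both times set 4 pools against 4. Aspm fell 2.65-fold (log2 -1.41 ± 0.10, adjusted p = 0.00867), Prnd 4.72-fold and the tendon gene Tnmd 3.38-fold, and the second probe set of Prnd gave 0.24. The MHC class II genes H2-Ab1, H2-Eb1 and H2-Aa fell 3.07-fold, 2.97-fold and 2.90-fold. Apol11b rose 4.70-fold, Stfa2l1 4.19-fold, the platelet gene Gp9 3.70-fold, Lcn2 3.13-fold, Ctxn3 2.82-fold and the acute-phase gene Saa3 2.71-fold.

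Of 26 cell cycle genes, 7 fell (16 adjusted over the list alone), with Top2a, Mki67, Ccnb2 and Cdk1 lower by 2.62-fold, 2.60-fold, 2.32-fold and 2.31-fold, and the call held with an estimated correlation (adjusted p = 0.0138). Lamb1 and Col15a1 fell among 14 basement membrane genes (11 adjusted over the list alone; adjusted p = 0.232 with an estimated correlation), and 19 of 22 matrix genes fell adjusted over the list alone (adjusted p = 0.306 with an estimated correlation). The monocyte chemokine receptor Ccr2 fell among 19 macrophage genes (13 adjusted over the list alone; adjusted p = 0.306 with an estimated correlation) and Tnmd among 10 tendon genes (5 adjusted over the list alone; adjusted p = 0.306 with an estimated correlation). Of 17 fibroblast genes, 12 fell adjusted over the list alone (adjusted p = 0.232 with an estimated correlation). Lcn2 rose among 12 neutrophil genes (7 adjusted over the list alone; adjusted p = 0.332 with an estimated correlation). Their median of 1.15 became 1.69 without 3 d overload pool 1, whose neutrophil score was 1.64 against -0.58 in its partner, and 0.55 without that partner. In the same average, platelet genes other than Gp9 and Pf4 had a median of 0.88, and red cell precursor genes other than Slc4a1 of 0.09. None of these passed, but Gp9, left out because its rise had been seen, did. Pf4, also left out, was higher with the inhibitor at 10 d but lower at 3 d. Matrix proteases and inhibitors had a median of -0.41 (3 fell adjusted over the list alone; adjusted p = 0.408 with an estimated correlation) and secretion genes of -0.11 (2 fell adjusted over the list alone; adjusted p = 0.408 with an estimated correlation). Without single arrays, medians ranged from -0.54 to -0.22 for protease, -0.15 to -0.07 for secretion, -1.09 to -0.59 for matrix, -0.68 to -0.42 for macrophage and -0.78 to -0.37 for tendon genes. The PDGF genes did not pass, with averages of -0.35 ± 0.12 for Pdgfra, -0.09 ± 0.11 for Pdgfrb, 0.02 ± 0.11 for Pdgfa, 0.29 ± 0.15 for Pdgfb, -0.46 ± 0.23 for Pdgfc and -0.23 ± 0.12 for Pdgfd.

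Averaged over the times, 14 genes rose and 50 fell, and at a common median 21 rose and 31 fell. The count of 64 became 341 without 10 d overload pool 1 and 7 without its partner, 25 and 15 without 3 d overload pools 1 and 2, 0 by limma and 6 without 3 d inhibitor pools 1 and 2, and 13 and 16 without 10 d inhibitor pools 1 and 2, and 2817 genes had an unadjusted p under 0.05 with all arrays. The protease call was lost without 3 d overload pool 1 (camera adjusted p = 0.118) and the secretion call without that pool (0.0635) or 10 d overload pool 2 (0.0709). Of the 19 genes named here, 18 passed without 10 d overload pool 1 and 0 to 10 in each other omission by limma, and Ccr2, Tnmd, Cdk1, Lamb1 and Col15a1 each passed in 1 of 10.

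Whether the inhibitor acted differently at 10 d and 3 d was tested as the difference of its effects. By limma, 0 genes passed and 1434 had an unadjusted p under 0.05. The smallest p values belonged to Pf4, a platelet chemokine (difference 1.73 ± 0.25), Csf3r (1.26 ± 0.19), Prdm8 (-1.31 ± 0.20), the small GTPase Gem (-2.15 ± 0.35), Adamts3 (-1.14 ± 0.19) and Trim62 (-1.38 ± 0.24), each with adjusted p = 0.516. Among lists, the difference had a median of -0.49 for basement membrane genes, and 7 of 14 passed adjusted over the list alone (adjusted p = 0.508 with an estimated correlation). Neutrophil genes differed by 2.09, and 6 of 12 passed adjusted over the list alone (adjusted p = 0.569 with an estimated correlation). This difference was 1.16 without 3 d overload pool 1, which had a neutrophil score of 1.64 against -0.58 in its partner, and 3.03 without that partner. At 3 d, S100a8 was at 3.90 and 3.87 log2 units in the inhibitor pools against 5.45 and 2.05 in overload pools 1 and 2. Retnlg was at 5.25 and 4.94 against 5.58 and 1.62, and Csf3r at 4.54 and 4.69 against 4.74 and 4.54. How far S100a8 and Retnlg changed with the inhibitor at 3 d therefore depended on overload pool 1. The cell cycle list differed by 0.09 and was not called (camera adjusted p = 0.247). Matrix (-0.50) and fibroblast genes (-0.32) were also called (adjusted p = 0.657 with an estimated correlation for each). So were immediate early (-0.35), fatty acid oxidation (-0.27), endothelial (-0.17) and cytokine genes (0.25; adjusted p = 0.613 with an estimated correlation for each) and pericyte genes (-0.30; adjusted p = 0.508 with an estimated correlation). Without single arrays the difference ranged from -0.93 to -0.08 for matrix, -0.39 to -0.14 for fibroblast, -0.62 to -0.08 for immediate early, -0.39 to -0.15 for fatty acid oxidation, -0.29 to -0.11 for endothelial, 0.08 to 0.33 for cytokine and -0.34 to -0.19 for pericyte genes. By limma, 14 genes passed without 3 d overload pool 2 and 2 without 10 d overload pool 1. Calls were lost without 3 d overload pool 1 (cytokine and pericyte genes, camera adjusted p = 0.521 and 0.0513), 3 d overload pool 2 (immediate early and fibroblast, 0.158 and 0.211), 3 d inhibitor pool 1 (fibroblast, 0.221), 3 d inhibitor pool 2 (cytokine and endothelial, 0.356 and 0.0560), 10 d overload pool 1 (cytokine and endothelial, 0.487 and 0.0601), 10 d overload pool 2 (matrix, immediate early and fibroblast, 0.984, 0.134 and 0.619), 10 d inhibitor pool 1 (cytokine and fibroblast, 0.163 and 0.0643) and 10 d inhibitor pool 2 (fibroblast, 0.114).

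Genes moved by overload were compared with genes moved by the inhibitor at the other time, which shares no arrays. The 10 d overload change and the 3 d inhibitor change correlated across genes at r = -0.305 (rho = -0.216). The 3 d overload change and the 10 d inhibitor change correlated at r = -0.206 (rho = -0.152), and at -0.019 without 10 d overload pool 2. Of the 865 genes higher after 10 d of overload, 84.0% were lower with the inhibitor at 3 d (median -0.33), against 44.2% of genes not called for 10 d of overload. Of the 2066 genes higher after 3 d, 66.7% were lower with the inhibitor at 10 d (median -0.17), against 47.0% of genes not called for 3 d of overload. Of genes lower with overload, 29.3% of those at 10 d and 41.8% of those at 3 d were lower with the inhibitor at the other time. At the same time, where the overload pools enter both changes, r was -0.442 at 3 d and -0.553 at 10 d against -0.499 in simulations of unchanged groups at each time, and the covariance minus the simulated one was -0.0581 and -0.0597. Inhibitor changes at 3 d and 10 d, which share no arrays, correlated at r = 0.255. Genes are not independent replicates, so no p is given for these correlations.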

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

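Which patterns to weigh, and the tests on the granulocyte precursor, endothelial and tendon lists, were chosen after the results were seen; the tests on blood lists, regrouped pools and single pools were fixed before their values were computed.

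Neutrophil genes were higher with the inhibitor at 10 d, where Lcn2 and Csf3r passed and the list was not called with an estimated correlation. The rise did not come from a single odd pool alone, because the lower inhibitor pool's score lay 2.08 above the higher pool without inhibitor. Its median ran from 1.97 to 2.59 without single arrays. Blood or marrow in these pools could account for the rise. Red cell precursor and platelet genes had a median change of 0.73 (0.29 to 1.09, 95% interval over members), without Slc4a1, Gp9 and Pf4, whose rise had been seen. Platelet genes carried it, with a median of 1.09 against 0.29 for red cell precursors. The members came from the same pools, so the interval does not measure the spread between pools. Granulocyte precursor genes of marrow changed less than neutrophil genes by a median difference of -1.88 (-2.98 to -0.58), which taken alone speaks against marrow, but they lay at 1.66 log2 units, near 1.5, below which the dimmest 30% of genes lie. That precursor test was written after the scores were seen and first excluded marrow. A condition on dim signal and then a margin of 1 log2 unit were added after the level was seen. Leaving marrow open thus rests on a choice that favours that explanation. Such transcripts can be detected: 3 d overload pool 1 had Elane at 5.21 and Mpo at 5.02 beside S100a8 at 5.45. The 10 d inhibitor pools had S100a8 at 4.72 and 4.78, but Elane at 1.75 and 1.33 and Mpo at 1.62 and 1.75. Ngp, also high in that 3 d pool (6.89), was at 5.37 and 4.88 in them. With 1 pool as the only reference, these values do not exclude marrow.

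Cell cycle genes were lower with the inhibitor at both times, and with an estimated correlation the list was called at 3 d but not at 10 d. If the inhibitor had lowered the share of all cells other than fibres, endothelial genes might have fallen alike. Their median changes were 0.20 at 3 d (0.09 to 0.28) and -0.26 at 10 d (-0.39 to 0.19), against -0.76 and -0.60 for cell cycle genes. Macrophage, fibroblast and tendon genes, however, were lower at both times. Without single arrays the macrophage median was -0.74 to -0.30 at 3 d and -0.85 to -0.27 at 10 d. The endothelial list cannot speak for these cells, so a smaller share of some cell types was left open. Over the 18 ways to regroup the pools within the times, 1, the real one, gave as many as 64 genes, and the highest other count was 0. So few regroupings could not give a small p. Most other regroupings also put pools with and without inhibitor into the same group. Any inhibitor effect then adds to the spread, so their counts of 0 are no measure of chance. A smaller share of dividing cells and fewer divisions per cell could not be told apart in pooled muscle.

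Matrix genes were lower with the inhibitor at 10 d, a list call that was lost with an estimated correlation. Less tendon in the dissected muscle could lower them, and tendon genes other than Fmod changed by 0.46 less than matrix genes (-0.44 to 0.79), which left this open. The direction did not come from a single pool alone, because the lower pool without inhibitor lay 0.63 above the higher inhibitor pool. The size did depend on single pools. Without single arrays the matrix median ran from -1.62 to -0.64, and it was smallest without 10 d overload pool 2.

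Other surprises were not tested further. With overload, 1348 genes differed between 10 d and 3 d. The inhibitor effect differed between the times in the immediate early (-0.35; -0.62 to -0.08 without single arrays), matrix (-0.50; -0.93 to -0.08), basement membrane (-0.49; -0.57 to -0.40), fatty acid oxidation (-0.27; -0.39 to -0.15), cytokine (0.25; 0.08 to 0.33), fibroblast (-0.32; -0.39 to -0.14), pericyte (-0.30; -0.34 to -0.19), endothelial (-0.17; -0.29 to -0.11) and neutrophil lists (2.09; 1.16 to 3.03), none of which was called with an estimated correlation. When every probe set was tested, 758 of the 19165 that did not stand for a gene passed at 3 d of overload (428 higher and 330 lower).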

How the results depend on the processing

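Omission of each array was fixed before the data were examined, and naming 3 d overload pool 1 among them for its marrow-type transcripts was chosen after its values were seen. Leaving out single arrays gave 2146 to 3850 genes at 3 d, 259 to 1232 at 10 d, 218 to 1096 between the times, 0 to 7 and 0 to 180 for the inhibitor at 3 d and 10 d, 0 to 341 averaged and 0 to 14 for the difference, and correlations across times of -0.316 to -0.019 and -0.324 to -0.213. The matrix median ran from -0.0223 to 0.72 between the times and from -0.93 to -0.0786 for the difference of inhibitor effects, with both ends set by the 10 d overload pools. An intensity trend gave 2097 genes at 10 d, 2450 between the times, 15 and 180 for the inhibitor at 3 d and 10 d, and 465 averaged. The compared groups alone gave 31, 202 and 3 genes at 10 d, between the times and for the inhibitor at 10 d, with fewer residual degrees of freedom. Without dim genes the averaged count was 100. Testing every probe set, which adds tests, gave 509 at 10 d, 540 between the times, and 0 for the inhibitor at 10 d and averaged. Over genes called for overload alone, the 10 d overload and 3 d inhibitor correlation was -0.536. Elsewhere the cause was not tested. Of 102 list calls, 70 held without each array, 67 with fry and 6 with an estimated correlation. Without dim genes 7 calls were lost (camera adjusted p): IGF and ribosome biogenesis at 3 d (0.113 and 0.0517), interferon response at 10 d (0.0648), matrix between the times (0.0545), basement membrane and secretion with the inhibitor at 3 d (0.0604 and 0.0949) and angiogenic factors with it at 10 d (0.0738). Quantile normalization again lost 4: IGF at 3 d (0.0556), interferon response at 10 d (0.0868), basement membrane with the inhibitor at 3 d (0.0515) and the cytokine difference (0.0518). A change of background correction and a strip block were not run, because scanner intensities and strips were not used here.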

Other observations

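The MHC class II genes were looked at after H2-Ab1, H2-Eb1 and H2-Aa appeared among the largest falls with the inhibitor. These genes present antigen on macrophages, dendritic cells and B cells. With 3 d of overload H2-Ab1 rose by 1.84, H2-Eb1 by 1.79 and H2-Aa by 1.42, and with 10 d they rose by 1.94, 2.08 and 1.69. The other 6 class II pathway genes looked at, with mean signals of 1.38 to 3.31 log2 units and so mostly dim, did not pass with the inhibitor. Of these 6, all were negative at 3 d (median -0.44), 5 in the averaged effect (median -0.30) and 3 at 10 d (median -0.19), and whether the pathway fell as a whole was left open. Ciita, which controls class II transcription and is among the 6, gave -0.69 averaged over the times (adjusted p = 0.336 from limma).

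Platelet genes had a median of 1.09 with the inhibitor at 10 d, red cell precursor genes of 0.29, granulocyte precursor genes of 0.37 and B cell precursor genes of 0.06. At 3 d these medians were 0.73, -0.15, -0.84 and 0.09, and overload pool 1, with its granulocyte precursor transcripts, entered them. No member passed at either time, with Slc4a1, Gp9 and Pf4 left out because their rise at 10 d had been seen. At 3 d only Gp9 was higher in both inhibitor pools (6.02 and 6.20 against 4.57 and 4.34). Pf4 was lower there, at 5.48 and 5.50 against 6.47 and 6.04. Slc4a1 was at 2.79 and 2.65 against 4.91 and 1.80. The 3 d platelet median thus leaves out a gene that was lower with the inhibitor. Staining of perfused muscle for Ly6g and Pf4 would tell whether the cells lie in tissue or in retained blood.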
